A study of Homo sapiens with 6 samples.

How the data were processed

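Total RNA from ACH-3P cells was extracted on silica columns, and biotin-labelled amplified RNA was made from 500 ng with an Affymetrix 3' IVT kit, per the labels' protocols. The deposited data hold log2 signals of 54675 probe sets on 6 arrays, with values from −2.85 to 17.29. The log base was inferred from this range, since no label gives it. How the authors summarised the probes, corrected the background and scaled the arrays is not given in the sources used here. The arrays' quantiles differ, so the deposited log2 values were not quantile normalized, and they were not centred per gene. The deposited values were used as they were. A 3' kit reads the 3' end of a transcript, and degraded RNA lowers the signal of probes far from it. Dim log2 signals are noisy, which widens the spread of genes of low abundance.

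Arrays were grouped by their titles into 3 control and 3 PRR15 shRNA arrays. Probe sets were named through the platform's annotation, with symbols updated through Entrez identifiers, which changed none; 54 identifiers of single-gene probe sets were not matched and kept the annotation's symbol. Of the probe sets, 62 were controls, 41091 had a single gene, 1801 had several and 11721 had none. Only those with 1 gene were used, and each of the 19775 genes was represented by its probe set with the highest mean over the 6 arrays. Of these genes, 10523 had several probe sets. No genome build is named, so no coordinates are given.

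The main comparison, PRR15 shRNA minus control, was fitted over all genes in limma (lmFit and eBayes, without trend or robust settings, and without covariates), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. PRR15 was also tested with a two-sided exact permutation test, for which 0.1 is the smallest p with 3 arrays against 3. A total of 31 gene lists with 901 distinct genes, 821 of them measured, was tested with camera at a preset correlation of 0.01. Of the genes not measured, 33 were only on probe sets shared between genes. Camera with an estimated correlation, camera on ranks and fry were run as alternatives, and each list was also counted with p adjusted over the list alone. The lists, tests and alternatives were fixed before the data were examined.

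The other alternatives were centring each array on its median, quantile normalization, leaving out the lowest 25% of genes or the dimmer genes (mean log2 signal below 7.49, leaving 9887), the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, trend and robust eBayes, array weights, the replicate number as a block and each array left out. All probe sets one by one and a minimum change of 2-fold were also run. The fit on the 9887 brighter genes was one of these alternatives. It is described in detail because genes passed in it, and that decision was taken after its count was seen. Fits with the mean 3' minus 5' log2 signal of ACTB and GAPDH as a covariate, fits without the 2 arrays of highest 3' minus 5' signal, and the other alternatives applied to the brighter genes were added after seeing the data.

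Genes were named by a rule fixed beforehand. It took PRR15, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and which were bright enough, then up to 4 members per list with the smallest p, or the 6 smallest p in each direction where none passed. None passed over all genes, so those 6 per direction are given, and the 12 per direction were taken from the brighter genes after the count there was seen.

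The procedure was tested on simulated data with the arrays' own means and spread. The fit over all 19775 genes recovered 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold, with 0 false calls. The fit over the 9887 brighter genes recovered 54 of 100 and 97 of 100, with 10 false calls. The list test found the 1 list shifted by 0.5 on the log2 scale, with 0 false calls among 31 lists. The simulated noise was independent between genes, so this gives no rate of false calls for lists of correlated genes. In the data the estimated correlation was 0.32 for p53 targets and 0.59 for cholesterol synthesis. The number of arrays limits the precision of every value. Software was R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and matplotlib 3.10.9 for figures.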

Results

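Messenger RNA was measured on Affymetrix expression arrays in ACH-3P, an established human trophoblast cell line of first-trimester origin. Trophoblast is the epithelial lineage that forms the outer layers of the placenta. Of the 6 arrays, 3 came from cells infected with a lentivirus that expressed a short hairpin RNA (shRNA) against PRR15, the gene of a proline-rich protein. The other 3 came from cells infected with a control lentivirus without any shRNA, so the groups differed both in PRR15 targeting and in the presence of a hairpin. The labels call the 3 samples of each group biological replicates but do not say what was kept separate, so the tests measure the spread between these samples. Values are the deposited log2 signals, each gene being read from 1 probe set, and 19775 genes were measured. The median signal of an array over all probe sets lay between 6.37 and 6.51. Across the 9887 brighter genes (mean log2 signal above 7.49) the arrays were less alike in level. Their median there was 10.45 in control 3 and 10.56 in PRR15 shRNA 1, and between 10.79 and 10.92 on the other arrays. Pearson's r between arrays ranged from 0.92 to 0.95 across all genes and from 0.963 to 0.993 across the brighter genes. Genes are not independent replicates, and r across genes describes only how alike the arrays were. The number of arrays limits the precision of every comparison.

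The 3' minus 5' signal, which depends on RNA integrity and on copying of the RNA, differed within both groups more than between them. The 3' minus 5' signal of ACTB and GAPDH, which grows when RNA is degraded or copied incompletely, averaged 1.84 on the log2 scale in control 3 and 1.50 in PRR15 shRNA 1. It lay between 0.36 and 0.74 on the remaining 4 arrays. The group means were 0.97 ± 0.77 in control and 0.95 ± 0.48 in PRR15 shRNA (SD, n = 3 each). The same 2 arrays had the highest mean signal of the spiked hybridisation controls, 14.77 and 14.19.

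**Figure D1:**
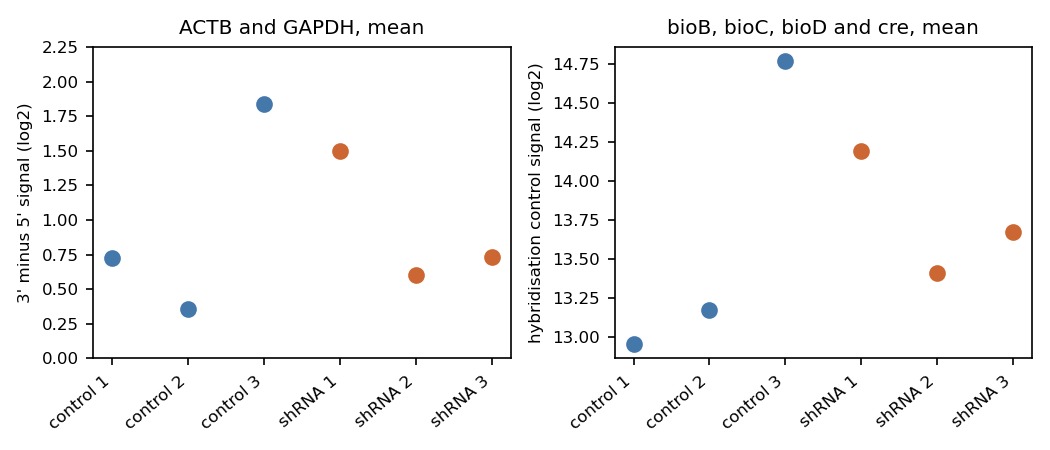
Left, mean 3' minus 5' log2 signal of the ACTB and GAPDH control probe sets on each array; right, mean log2 signal of the bioB, bioC, bioD and cre hybridisation controls, on an axis that does not start at 0. Each point is 1 array, blue for control and orange for PRR15 shRNA. Control 3 (1.84) and PRR15 shRNA 1 (1.50) have the highest 3' minus 5' values.

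The targeted transcript was measured first, to check the labels. PRR15, read by probe set 226961_at, had a log2 signal of 8.10 ± 0.36 in control and 7.40 ± 0.18 in PRR15 shRNA (SD, n = 3 each). The difference was −0.70 (SE 0.25, 95% interval −1.33 to −0.07), which leaves 61.6% of the control signal (39.8% to 95.5%). All 3 shRNA arrays lay below all 3 control arrays, for which the two-sided exact permutation test gave p = 0.1, the smallest p this design allows. By limma the adjusted p was 0.513 over all genes and 0.161 over the brighter genes, so the lower signal did not pass. With the 3' minus 5' value as a covariate, a fit chosen after seeing the data, limma's adjusted p over the brighter genes was 0.0273.

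The comparison asked which transcripts differed between cells with PRR15 targeted and control cells. Among the 9887 brighter genes, 72 rose and 103 fell with PRR15 shRNA by limma at an adjusted p under 0.05, and 121 of these 175 changed at least 2-fold. Over all 19775 genes limma called 0, with a smallest adjusted p of 0.0901, and 1804 genes had an unadjusted p under 0.05, where about 989 would be expected on average if no gene differed. The spread within groups was larger among dim genes, with a median residual SD of 1.08 on the log2 scale against 0.25 among the brighter genes. The groups did not overlap for the 175 genes, nor for 21.9% of the brighter genes, where chance gives 10% on average. Genes are not independent, so a single split can lie far from these averages. The split of control 1, control 2 and PRR15 shRNA 2 from the other arrays gave 1770 genes with an unadjusted p under 0.05. It left 30.5% of the brighter genes without overlap, so neither value of the real split is shown to exceed chance. Genes said to have risen or fallen passed limma among the brighter genes. Other probe sets of a named gene are described where one differed in sign or by at least 1 on the log2 scale.

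The 12 largest rises among the brighter genes were between 2.81-fold and 4.67-fold. IP6K3, an inositol hexakisphosphate kinase, rose 4.67-fold, from 7.45 ± 0.16 to 9.67 ± 0.20 (SD, n = 3 each). CRYAB, a small heat shock protein, rose 4.56-fold, from 9.05 ± 0.37 to 11.23 ± 0.53. SMPD3, a neutral sphingomyelinase, rose by 2.03 on the log2 scale (SE 0.30). VTCN1, which encodes the T-cell inhibitory protein B7-H4, rose 3.60-fold, from 7.24 ± 0.07 to 9.09 ± 0.04. GDF15, a stress-induced cytokine, rose 3.59-fold and TNFSF10, the death ligand TRAIL, rose 3.05-fold. EPM2A, the glycogen phosphatase laforin, rose 3.37-fold and PAAF1, which binds ATPases of the proteasome, rose 3.24-fold. KITLG, the ligand of the KIT receptor, rose 2.93-fold, REEP6 2.90-fold and TCEAL1 2.81-fold. MYLK3, a myosin light chain kinase, rose 3.11-fold on its brightest probe set, while its 4 other probe sets ranged from −1.41 to 2.05 on the log2 scale. The other probe sets of KITLG ranged from 0.02 to 2.13 and those of EPM2A from 0.46 to 1.45, against 1.55 and 1.75 on the brightest. That of SMPD3 gave 0.72 and that of PAAF1 0.40. GDF15 was read from an _x_at probe set, a type whose probes are shared with similar transcripts. Its other probe sets gave 0.99 and 1.29 against 1.85. The adjusted p of these 12 genes ran from 0.00568 for VTCN1 and IP6K3 to 0.0452 for TCEAL1 by limma.

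The 12 largest falls among the brighter genes were between 3.08-fold and 4.45-fold. GLRX, the thiol-reducing enzyme glutaredoxin, fell 4.45-fold, from 12.34 ± 0.27 to 10.18 ± 0.20 (SD, n = 3 each). The metallothioneins MT1HL1 and MT1X, which bind zinc and other metals, fell 3.99-fold and 3.97-fold, on _x_at probe sets, whose probes are shared with similar transcripts. KRT80, an epithelial keratin, fell 3.72-fold, from 9.98 ± 0.04 to 8.09 ± 0.23. CSRP1, a LIM protein of the actin cytoskeleton, fell 3.48-fold, and CCDC88A, the actin-binding protein girdin, fell 3.33-fold. ITGA2, the collagen-binding integrin alpha 2, fell 3.28-fold, from 11.09 ± 0.14 to 9.38 ± 0.35. SPRED1 and DUSP4, both inhibitors of the ERK MAP kinase pathway, fell 3.69-fold and 3.08-fold. UQCC3, an assembly factor of respiratory complex III, fell 3.57-fold. KCTD6 fell 3.87-fold and EEF1AKMT2, a methyltransferase of the translation elongation factor, fell 3.12-fold. On the log2 scale another probe set of GLRX gave −1.02 against −2.15, another of KCTD6 gave −0.87 against −1.95, and those of SPRED1 ranged from −1.90 to −0.81. Limma's adjusted p for these 12 genes ran from 0.00877 for GLRX and KRT80 to 0.0399 for CCDC88A.

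**Figure D2:**
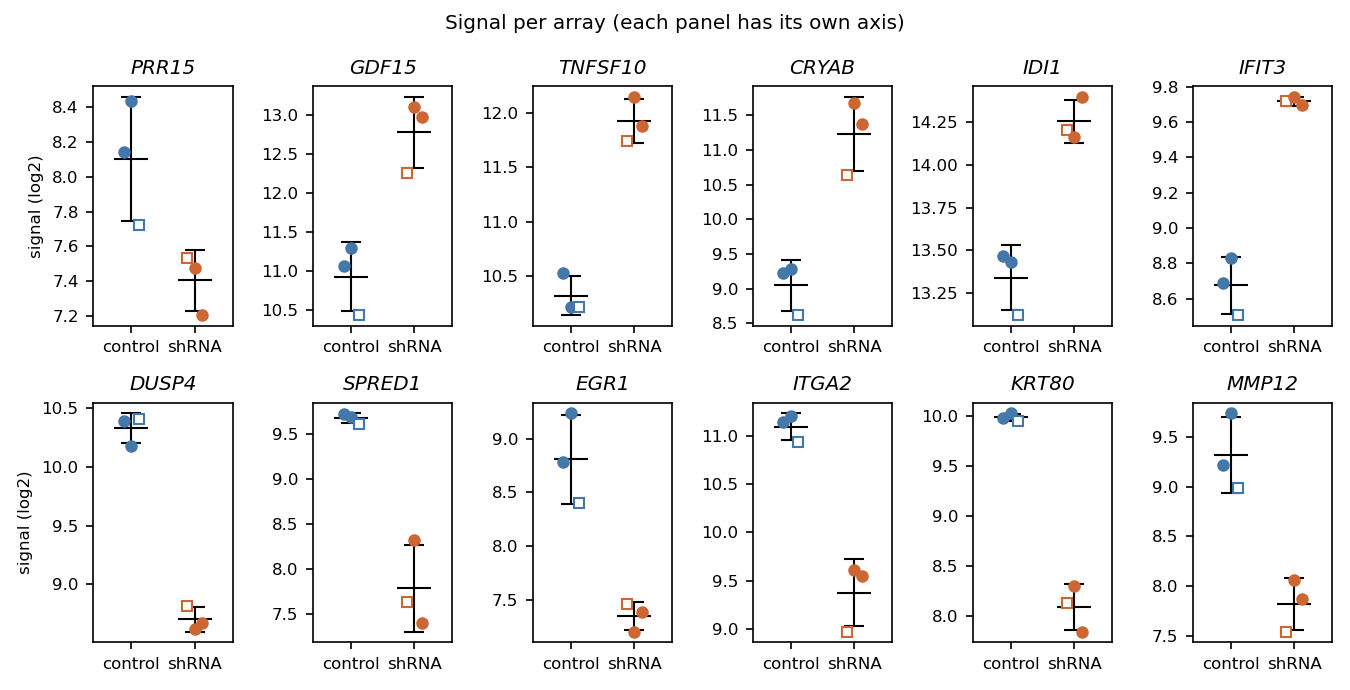
Log2 signal of 12 genes on each array, control in blue and PRR15 shRNA in orange, with the group mean (wide line) and SD (n = 3 each); each panel has its own axis, which does not start at 0. Open squares mark control 3 and PRR15 shRNA 1, the arrays with high 3' minus 5' values. In every panel the 3 shRNA arrays lie on one side of the 3 control arrays, and PRR15 shows the smallest change, −0.70.

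The count of 175 depended on single arrays. It was 0 without control 1 and 0 without PRR15 shRNA 3, 11 without control 2, 18 without PRR15 shRNA 1, 5 without PRR15 shRNA 2 and 607 without control 3. It was 3 (IP6K3 and VTCN1 higher, KRT80 lower) when the probe sets of each gene were averaged and 35 without probe sets ending in _x_at or _s_at. It was 1204 after quantile normalization and 1507 with array weights. Chosen after seeing the data, the fit with the 3' minus 5' covariate called 1872 genes, 850 higher and 1022 lower, including all 175, and the fit without control 3 and PRR15 shRNA 1 called 1086, including 174 of them.

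Over all genes, the 6 smallest p-values in each direction did not pass, with adjusted p between 0.0901 and 0.105 by limma. The higher genes were VTCN1, IP6K3, CHRDL2, GALR2, LOC101927531 and TRDN-AS1. The lower genes were CCDC63, MYO1G, ZNF804A, LINC01442, SCAT1 and TMEM92-AS1. Of these 12 genes, 10 lay below the brighter range. CCDC63 had the smallest p, with 6.22 ± 0.10 in control and 2.34 ± 0.29 in PRR15 shRNA (SD, n = 3 each). A second probe set of MYO1G gave −0.14 against −2.72 on the first, and that of TMEM92-AS1 gave 1.22 against −2.76.

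Gene lists fixed before the data were examined were then tested. Of 31 lists, 15 were shifted relative to the other genes by limma's camera test with its preset correlation of 0.01, 8 towards higher and 7 towards lower signal in PRR15 shRNA. With a correlation estimated per list, 0 of the 31 passed, the smallest adjusted p being 0.818. In fry, which tests whether a list's genes move one way without comparing them with other genes, 0 passed (smallest adjusted p = 0.356). In fry's mixed test, for change in either direction, 14 passed, and these were not all lists that camera called. The death-promoting, TGF-beta, imprinted and epithelial junction lists passed it without a camera call (adjusted p = 0.00314, 0.0119, 0.0145 and 0.028). The mesenchymal, ribosomal protein, lysosomal, ATF4 and YAP lists, called by camera, did not (adjusted p = 0.497, 0.414, 0.121, 0.0608 and 0.0588). With the probe sets of each gene averaged 6 lists passed, namely targets of p53, ATF4 and NRF2 and the cholesterol, mesenchymal and lysosomal lists. Without probe sets ending in _x_at or _s_at 3 did, namely p53 targets, cholesterol synthesis and NRF2 targets. Without PRR15 shRNA 3 the number was 7. Adjusted over all genes, 0 members of any list passed. A call is said to be lost where the adjusted p of a list rose above 0.05, whatever its median. List medians are given without subtracting the median change over all genes, which was 0.01 in the main setting. That median over all genes was −0.11 without control 3, 0.08 without PRR15 shRNA 1 and −0.06 with array weights. The lists held 608 of the brighter genes, of which 9 rose and 9 fell.

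**Figure D3:**
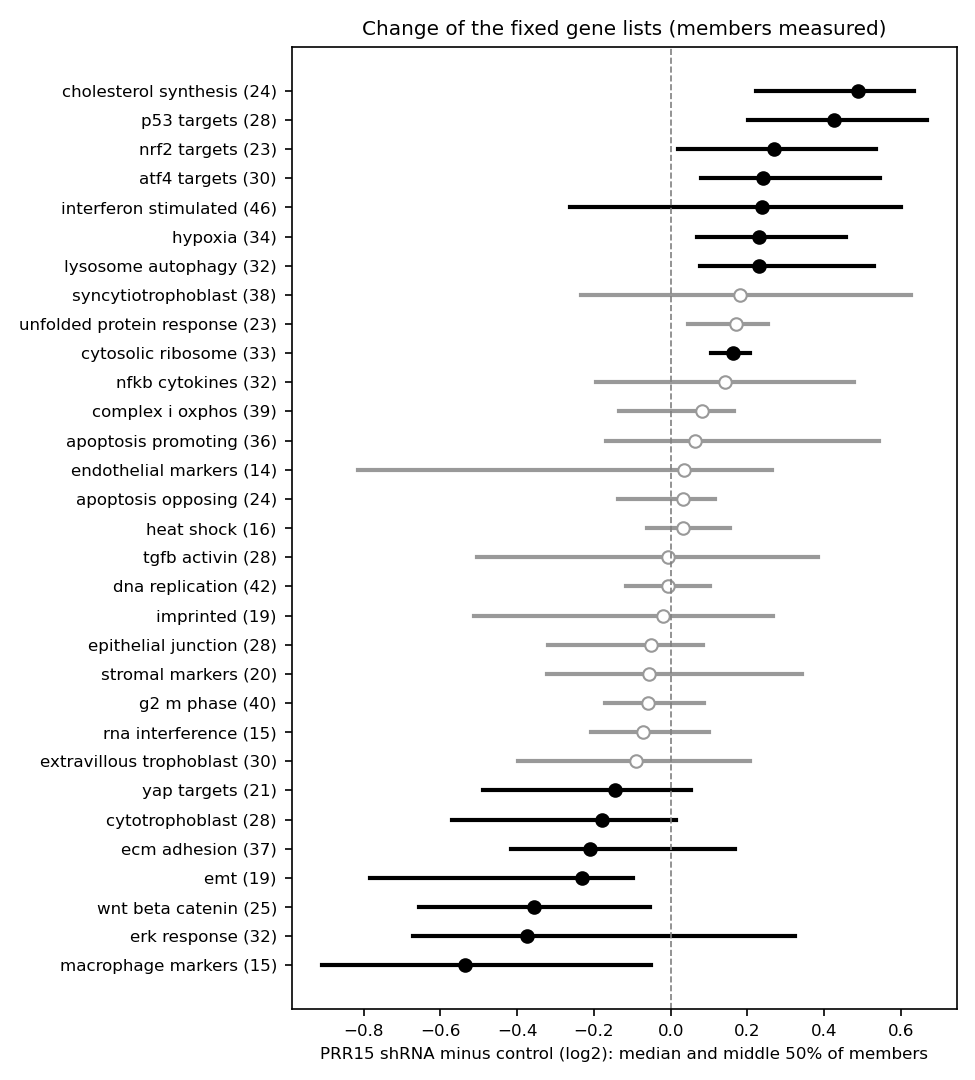
Change of the 31 gene lists, PRR15 shRNA minus control on the log2 scale; circles are medians over the measured members (number in brackets) and lines span the middle 50% of members. Black marks the 15 lists past the preset-correlation camera test (adjusted p under 0.05) and grey the others; none passed with an estimated correlation. Cholesterol synthesis (0.49) and p53 targets (0.43) have the highest medians, macrophage markers (−0.54) the lowest. Only 2 of the 15 macrophage markers lie among the brighter genes.

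Targets of the tumour suppressor p53 were shifted higher in PRR15 shRNA. Of 28 measured members 25 had a higher mean and 3 a lower one, with a median difference of 0.43 on the log2 scale (camera adjusted p = 5.47e-07; adjusted p = 0.818 with an estimated correlation). Among the 24 brighter members, GDF15 and SESN1, a stress-induced sestrin, rose and 0 fell. SESN1 rose 1.84-fold, from 12.15 ± 0.22 to 13.03 ± 0.02 (SD, n = 3 each). CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by 0.93 (SE 0.19) and TP53INP1 by 1.38 (SE 0.29), with limma adjusted p of 0.0553 and 0.0598. With the 3' minus 5' covariate, 14 of the 24 passed as higher and 0 as lower. Without control 3 and PRR15 shRNA 1 together, 7 passed as higher and 0 as lower. Adjusted over the list alone, 0 passed.

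Genes of cholesterol and fatty acid synthesis were also shifted higher. Of 24 measured members 22 had a higher mean, with a median difference of 0.49 (camera adjusted p = 8.27e-06; adjusted p = 0.818 with an estimated correlation). IDI1, which makes the isoprenoid precursor dimethylallyl diphosphate, rose 1.89-fold, from 13.34 ± 0.19 to 14.26 ± 0.13 (SD, n = 3 each), and was the 1 of 22 brighter members that passed. The sterol oxidase MSMO1 differed by 0.75, the squalene epoxidase SQLE by 0.62 and the fatty acid desaturase SCD by 0.56, none past the threshold. The other probe sets of SQLE ranged from −0.03 to 0.53. IDI1 was read from an _x_at probe set, and its other probe sets ranged from 0.49 to 0.76 against 0.92. With the 3' minus 5' covariate 13 of the 22 passed, all higher, and without control 3 and PRR15 shRNA 1 together 7 passed, all higher. Adjusted over the list alone, 0 passed.

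Interferon-stimulated genes were shifted higher, with a higher mean in 30 of 46 measured members and a lower one in 16. The median difference was 0.24 (camera adjusted p = 0.0162; adjusted p = 0.818 with an estimated correlation). IFIT3 and IFIT5, which encode antiviral tetratricopeptide proteins, rose 2.06-fold and 2.43-fold, and HERC5, the ligase of ISG15, rose 2.08-fold. RIGI, a sensor of viral RNA, differed by 0.68 and did not pass, and its other probe sets gave 0.01 to 0.16. Of the 23 brighter members, 3 rose and 0 fell. Adjusted over the list alone, IFIT3 and HERC5 passed. The call was lost without control 3 (median 0.09, adjusted p = 0.0578), with probe sets averaged (median 0.11, adjusted p = 0.0658) and without _x_at and _s_at probe sets (median 0.12, adjusted p = 0.207). The median was 0.15 without PRR15 shRNA 2 and with array weights, 0.09 without control 3 and PRR15 shRNA 1 together, and 0.39 among the brighter members.

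Genes that respond to ERK signalling were shifted lower, with a lower mean in 21 of 32 measured members. The median difference was −0.37 (camera adjusted p = 0.00621; adjusted p = 0.818 with an estimated correlation). DUSP4, SPRED1 and EGR1 fell, and 0 of the 21 brighter members rose. EGR1, an immediate early transcription factor, fell 2.73-fold, from 8.81 ± 0.41 to 7.36 ± 0.13 (SD, n = 3 each). KLF6, another early response transcription factor, differed by −0.71 and did not pass, and its other probe sets ranged from −0.61 to 1.04. The same 3 genes passed when adjusted over the list alone. With the 3' minus 5' covariate, 12 of the 21 brighter members passed as lower and 2 as higher. Without control 3 and PRR15 shRNA 1 together, 10 passed as lower and 2 as higher. The call was lost with probe sets averaged (median −0.24, adjusted p = 0.0566) and without _x_at and _s_at probe sets (median −0.07, adjusted p = 0.207). The median was −0.18 without PRR15 shRNA 1 (adjusted p = 0.0119) and −0.59 among the brighter members.

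Lists of adhesion and mesenchymal genes were also shifted lower, with medians nearer to 0 than that of the ERK list. Their means, −0.26 and −0.48, were not nearer to 0 than its mean of −0.21. Extracellular matrix and adhesion genes had a median of −0.21, with a lower mean in 23 of 37 members (camera adjusted p = 0.0168). ITGA2 was the member of this list that fell, and adjusted over the list alone ITGA2 and the matrix protein THBS1 passed, the other probe sets of THBS1 ranging from −1.45 to 2.36. COL5A1, a fibrillar collagen, differed by −1.0 and did not pass. Genes of the epithelial-mesenchymal transition had a median of −0.23 (adjusted p = 0.0143), with 0 passing and a difference of −0.81 for the transcription factor TWIST1. Only 6 of its 19 measured members lay among the brighter genes. With an estimated correlation both lists had an adjusted p = 0.818. The adhesion call was lost without PRR15 shRNA 1 (median −0.12, adjusted p = 0.0711), without PRR15 shRNA 3 (median −0.19, adjusted p = 0.071), without control 3 and PRR15 shRNA 1 together (median −0.24, adjusted p = 0.0893), with probe sets averaged (median −0.03, adjusted p = 0.194), without _x_at and _s_at probe sets (median −0.22, adjusted p = 0.121) and on ranks (adjusted p = 0.0527). Its median was −0.32 without control 3 and −0.35 without PRR15 shRNA 2. The mesenchymal call was lost without the lowest 25% of genes (median −0.14, adjusted p = 0.0754), without the dimmer genes (median −0.18, adjusted p = 0.131), without PRR15 shRNA 1 (median −0.20, adjusted p = 0.0714), without control 3 and PRR15 shRNA 1 together (median −0.48, adjusted p = 0.102) and without _x_at and _s_at probe sets (median −0.25, adjusted p = 0.207). Its median was −0.38 without control 3 or without PRR15 shRNA 3, and −0.35 with array weights.

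Lists of Hippo pathway targets and of Wnt pathway genes were also shifted lower. Targets of YAP, the Hippo pathway's effector, had a median of −0.15 (adjusted p = 0.0443), and FJX1 and IGFBP3 fell 2.23-fold and 2.10-fold. Wnt and beta-catenin genes had a median of −0.36 (adjusted p = 0.0267) with 0 passing. AXIN2, a feedback target of Wnt signalling, differed by −1.07 on its brightest probe set and by 0.28 as the mean of its probe sets (others −0.24 to 1.88), and APC by −0.73. DKK1, also in the Wnt list, differed by 0.85 at a dim signal, and 6 of the 25 measured members had a higher mean. With an estimated correlation both lists had an adjusted p = 0.818. The YAP call was lost without control 2 (median −0.08, adjusted p = 0.246), PRR15 shRNA 2 (median −0.19, adjusted p = 0.075) or PRR15 shRNA 3 (median −0.06, adjusted p = 0.192), with probe sets averaged (median −0.15, adjusted p = 0.0867), without _x_at and _s_at probe sets (median −0.12, adjusted p = 0.211) and on ranks (adjusted p = 0.0853), and its median was −0.24 with array weights. The Wnt call was lost without control 2 (median −0.35, adjusted p = 0.0857), PRR15 shRNA 2 (median −0.21, adjusted p = 0.185) or PRR15 shRNA 3 (median −0.42, adjusted p = 0.0596), with probe sets averaged (median −0.30, adjusted p = 0.157) and without _x_at and _s_at probe sets (median −0.33, adjusted p = 0.233).

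Trophoblast markers were examined for each of the main cell types of the lineage. Cytotrophoblast genes, which mark the proliferating progenitor layer, were shifted lower, with a median of −0.18 and a lower mean in 20 of 28 members (camera adjusted p = 0.0194; adjusted p = 0.818 with an estimated correlation). EGFR, the epidermal growth factor receptor, differed by −0.77 on its brightest probe set and by 0.16 as the mean of its 9 probe sets (others −0.47 to 1.66), and PAGE4 by −1.0, neither past the threshold. The call was lost without PRR15 shRNA 3 (median −0.15, adjusted p = 0.0993), without control 3 and PRR15 shRNA 1 together (median −0.15, adjusted p = 0.0591), with probe sets averaged (median −0.22, adjusted p = 0.0939) and without _x_at and _s_at probe sets (median −0.15, adjusted p = 0.207). Syncytiotrophoblast genes, which mark the fused hormone-secreting layer, had a median of 0.18 and a higher mean in 26 of 38 members, and missed the threshold (adjusted p = 0.0713). They passed without control 2 (median 0.30, adjusted p = 0.016) and with the 3' minus 5' covariate (0.049), and their median was 0.11 without PRR15 shRNA 3. ERVW-1, the fusion protein syncytin-1, differed by 0.48 and did not pass. Extravillous trophoblast genes had a median of −0.09 (adjusted p = 0.293). They passed as lower without control 3 (median −0.29, adjusted p = 0.0481), and their median was 0.06 without control 2 and 0.05 without PRR15 shRNA 1. MMP12, a metalloproteinase in that list, fell 2.82-fold, from 9.32 ± 0.38 to 7.82 ± 0.26 (SD, n = 3 each).

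Several stress and metabolic lists were shifted higher by small amounts. The median was 0.24 for targets of ATF4, the transcription factor of the integrated stress response (camera adjusted p = 0.00613), and 0.23 for hypoxia genes (0.0088). It was 0.27 for targets of the oxidant-responsive factor NRF2 (0.0143) and 0.23 for lysosome and autophagy genes (0.0107). With an estimated correlation the adjusted p was 0.818 for the first 3 lists and 0.849 for the lysosomal one. No member of these 4 lists passed. The amino acid transporter SLC7A11, a member of both the ATF4 and NRF2 lists, differed by 0.87, and VEGFA, in both the ATF4 and hypoxia lists, by 0.67. ASNS, the asparagine synthetase, differed by 0.57, the mitophagy receptor BNIP3L by 0.89, the ferritin light chain FTL by 0.48 and the lysosomal membrane protein LAMP1 by 0.53. Some members went the other way. WARS1, in the ATF4 list, differed by −0.67 and ATG14, in the lysosomal list, by −0.52. Means were lower in 7 of 30 ATF4 targets, 7 of 34 hypoxia genes, 6 of 23 NRF2 targets and 7 of 32 lysosomal genes. CA12, a carbonic anhydrase, differed by 0.88 on its brightest probe set, while its 6 other probe sets ranged from −0.76 to 1.28. Without control 3 the median was 0.10 for ATF4 targets, 0.11 for hypoxia genes and 0.09 for lysosomal genes. Without PRR15 shRNA 2 it was 0.13 for ATF4 targets and 0.12 for lysosomal genes, whose call was then lost (adjusted p = 0.06). Without control 3 and PRR15 shRNA 1 together it was 0.16 for ATF4 targets and 0.13 for NRF2 targets, and with array weights it was 0.12 for hypoxia, 0.15 for NRF2 and 0.14 for lysosomal genes. Without PRR15 shRNA 3 the call was lost for NRF2 targets (median 0.19, adjusted p = 0.0686) and lysosomal genes (median 0.20, adjusted p = 0.071). With probe sets averaged it was lost for hypoxia genes (median 0.15, adjusted p = 0.194), and without _x_at and _s_at probe sets for ATF4 targets (median 0.27, adjusted p = 0.106), hypoxia genes (median 0.23, adjusted p = 0.106) and lysosomal genes (median 0.23, adjusted p = 0.234).

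Cytosolic ribosomal protein genes had a median of 0.16, with a higher mean in 31 of 33 members (adjusted p = 0.0143; adjusted p = 0.818 with an estimated correlation), and RPLP1 differed by 0.32. Their call was lost after quantile normalization, with a median of 0.03 (adjusted p = 0.728), and without control 1, control 2, PRR15 shRNA 1 or PRR15 shRNA 3 (medians 0.12, 0.09, 0.13 and 0.15, adjusted p = 0.246, 0.323, 0.139 and 0.0861). It was also lost with probe sets averaged (median 0.14, adjusted p = 0.194) and without _x_at and _s_at probe sets (median 0.13, adjusted p = 0.406).

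Genes of cell division were not detectably shifted. The 40 genes of G2 and M phase, all among the brighter genes, had a median of −0.06 and a mean of −0.07 ± 0.22 (SD over members; adjusted p = 0.293). KIF11, a mitotic kinesin, differed by −0.74 and did not pass. The 42 measured genes of DNA replication had a median of −0.01 (adjusted p = 0.98), and the helicase subunit MCM5 differed by −0.53. Death-promoting genes had a median of 0.06 (adjusted p = 0.382), with TNFSF10 the 1 of 28 brighter members that rose and HRK differing by −1.04, its other probe sets ranging from −1.05 to 0.51. Death-opposing genes had a median of 0.03 (adjusted p = 0.923) and heat shock genes a median of 0.03 (adjusted p = 0.395), and CRYAB, which belongs to both, rose. Adjusted over the list alone, TNFSF10 and CRYAB passed in these lists. With single arrays left out, each of these 5 medians lay on both sides of 0, between −0.14 (G2 and M phase, without control 3) and 0.14 (death-opposing genes, without PRR15 shRNA 1), and 0 of the lists passed.

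The remaining stress, signalling and epithelial lists did not pass the camera test. The median was 0.17 for the unfolded protein response (adjusted p = 0.0748), in which the chaperone cofactor DNAJB9 differed by 0.71. That list passed after quantile normalization (0.0387), with trend and robust eBayes (0.0222), with the 3' minus 5' covariate (0.0171) and without control 2 (median 0.25, adjusted p = 0.0476). Its median was 0.07 without control 3 and 0.08 without PRR15 shRNA 2. The median was 0.08 for genes of oxidative phosphorylation (0.533) and −0.05 for epithelial junction genes (0.159). NF-kappaB target and cytokine genes had a median of 0.14 (0.313). The chemokine CXCL8 passed when adjusted over that list alone, at a dim signal of 2.22 ± 0.68 in control and 5.77 ± 0.18 in PRR15 shRNA (SD, n = 3 each), and its other probe set gave −1.64. Genes of TGF-beta and activin signalling had a median of −0.01 (0.644), and BAMBI, a decoy receptor of that family, fell 2.04-fold. Genes of RNA interference had a median of −0.07 (0.449), and TNRC6B, a partner of Argonaute proteins, fell 1.96-fold and passed adjusted over the list alone. Imprinted genes had a median of −0.02 (0.791), and PEG3, a paternally expressed zinc finger gene, rose 2.02-fold. With single arrays left out, the medians of these last 6 lists each lay on both sides of 0, between −0.26 (TGF-beta, without control 3) and 0.25 (NF-kappaB, without control 2), and 0 of the 6 passed.

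Markers of other cell types were mostly dim. The samples came from a trophoblast cell line, so these values do not measure other cells. Macrophage markers were shifted lower, with a median of −0.54 and a lower mean in 11 of 15 members (camera adjusted p = 0.0269; adjusted p = 0.818 with an estimated correlation). Only 2 of the 15 lay among the brighter genes and 0 passed. CSF1R, the macrophage colony-stimulating factor receptor, had 10.19 ± 0.26 in control and 9.34 ± 0.10 in PRR15 shRNA (SD, n = 3 each). LYZ, lysozyme, differed by −1.84 at a dim signal, and its other probe set gave 0.25. The call was lost without control 2, control 3, PRR15 shRNA 2 or PRR15 shRNA 3 (medians −0.27, −0.99, −0.46 and −0.65, adjusted p = 0.0627, 0.058, 0.0821 and 0.0861). It was also lost with probe sets averaged (median −0.44, adjusted p = 0.0891), without _x_at and _s_at probe sets (median −0.24, adjusted p = 0.207) and with trend and robust eBayes (median −0.54, adjusted p = 0.0504). Stromal markers had a median of −0.06 and a mean of 0.10, opposite in sign (adjusted p = 0.98), and the collagen COL1A1 differed by −0.55, its other probe sets ranging from −0.65 to 0.07. Endothelial markers had a median of 0.03 and a mean of −0.17, also opposite in sign (adjusted p = 0.533), and the endothelial cadherin CDH5 differed by −0.73. With single arrays left out, the stromal median ranged from −0.24 without PRR15 shRNA 2 to 0.17 without PRR15 shRNA 1, and the endothelial median from −0.55 without PRR15 shRNA 3 to 0.08 without control 2.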

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

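The probe sets described here were outside the comparison of genes, and their test was chosen after the data were seen. Among 13522 probe sets with no gene or several genes in the annotation, 2551 had a mean log2 signal above 7.49, and 4 of these passed limma at an adjusted p under 0.05, 3 higher and 1 lower with PRR15 shRNA. Without the filter on dim probe sets 0 passed, with 835 at an unadjusted p under 0.05. Of those with no gene, 237563_s_at differed by 1.89 on the log2 scale (SE 0.17, adjusted p = 0.008) and 232569_at by −1.37 (SE 0.18, adjusted p = 0.0425). Of those with several genes, 221646_s_at differed by 2.20 (SE 0.29) and 218570_at by 1.43 (SE 0.18), both with an adjusted p of 0.0425. No explanation was tested for these probe sets. Groups of 3 arrays are too small for a test of outlying samples, and the design has a single contrast, so no difference between contrasts could be examined.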

How the results depend on the processing

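The fits with the 3'/5' covariate or without control 3 and PRR15 shRNA 1, and the alternatives applied to the brighter genes, were chosen after seeing the data. Over all genes limma called 0 in the main setting; it called 3 after quantile normalization (0 higher, 3 lower: CCDC63, MYO1G and GLRX), 50 with trend and robust eBayes (22 higher, 28 lower), 1 with array weights (CCDC63, lower; GLRX and CCDC63 were named here after their values were seen) and 175 with the dimmer genes left out (72 higher, 103 lower). It called 0 in the other settings, each array left out included. Among the brighter genes the count of 175 became 1204 after quantile normalization (603 higher, 601 lower), 3 with probe sets averaged (2 and 1), 35 without _x_at and _s_at probe sets (13 and 22), 1507 with array weights (417 and 1090), 1872 with the covariate (850 and 1022) and 1086 without the 2 arrays (361 and 725). With each array left out it ranged from 0 to 607 (higher 0 to 124, lower 0 to 483). It was 0 without control 1 or PRR15 shRNA 3 and 607 without control 3. The median change over all genes was itself −0.11 on the log2 scale without control 3. Without PRR15 shRNA 2 the 5 genes were GLRX, IP6K3, KRT80, SPRED1 and VTCN1. The cause of these changes was not tested. The PRR15 difference stayed below 0 in every setting run, from −0.53 to −0.95, and its adjusted p over all genes stayed above 0.05. The number of shifted lists, 15, was 6 with probe sets averaged, 3 without _x_at and _s_at probe sets, 0 with an estimated correlation, 0 with fry and 7 to 14 with each array left out (7 without PRR15 shRNA 3). P53 targets and cholesterol synthesis each kept their call in 18 of 20 alternatives, losing it with the estimated correlation and fry. Of 1306 alternatives counted for other named genes, 1240 kept direction and side of the threshold, 64 newly passed and 2 turned. These 2 turned as the mean of their probe sets, where AXIN2 differed by 0.28 and EGFR by 0.16, the cause of which was not tested. With the replicate number as a block, limma called 0 over all genes and 0 among the brighter genes (0 higher, 0 lower), and 12 lists, without the interferon, adhesion and YAP lists (adjusted p = 0.0714, 0.0614 and 0.0751). Same-numbered arrays deviated from their group means with r of −0.02, 0.03 and −0.03 across all genes and of −0.24, 0.28 and −0.25 across the brighter genes. Not every pair lay above 0.1, and not every array correlated best with its own number, so these values gave no sign of pairing. With 3 arrays per group they cannot exclude that same-numbered arrays were prepared together. The alternative with a pseudocount was not run, since the values are on a log scale. Dim signal limits what can be seen: the median residual SD was 1.08 below the brightness limit and 0.25 above it.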

Other observations

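The tests of RNA integrity, of hairpin sensing and of other splits of the arrays for the gene counts over all genes and the brighter genes and for the lists were chosen after the results were seen; the other tests had their outcome written down first. Genes of ribosome assembly, a list written after the gene results were seen and without the member already seen to differ, were lower with PRR15 shRNA in 22 of 26 measured members. Their median was −0.15 on the log2 scale (camera adjusted p = 0.0393 over the 3 lists added; adjusted p = 0.658 with an estimated correlation), and 0 of the 26 passed singly. Cytosolic ribosomal protein genes went the other way, with a median of 0.16 and 31 of 33 higher. Their call was lost after quantile normalization, and the processing alternatives were not run on the ribosome assembly list. Further targets of the FOXO transcription factors, tested because SESN1 and TNFSF10, known targets of these factors that were left out of the list, rose, had a median of 0.12 with 12 of 19 higher. Of the 13 brighter members 0 passed. Camera gave an adjusted p of 0.338 for them, which leaves a FOXO response open. The other metallothioneins and zinc response genes, tested because MT1X and MT1HL1 fell, had a median of −0.23 with 5 of 9 lower. The 5 lower, named after their values were seen, were MT1E (−0.55), MT1F (−0.56), MT1G (−0.28), the dim MT1M (−0.23) and MT2A. The 4 higher were the dim MT3 and MT4 and the zinc response genes MTF1 and SLC30A1. Camera gave an adjusted p of 0.338 here too, so a change of the whole family stays open. In this list MT2A, named after its value was seen, fell among the brighter genes, by 1.25 on the log2 scale. Its limma adjusted p of 0.049978 lay just under the threshold. Whether the probes of these family members are shared with those of MT1X or MT1HL1 was not examined.

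The absence of calls over all genes beside 175 among the brighter genes may come from dim probe sets and from the number of genes tested. When the p-values of the all-gene fit were adjusted over the brighter genes alone, 0 genes passed, so the pooled spread rather than the number of tests alone held them back. The prior degrees of freedom of limma were 1.51 over all genes and 4.26 over the brighter genes. When the p-values of the brighter-gene fit were adjusted over all genes, 16 passed, so both explanations remain.

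For the genes that passed among the brighter genes, the part of the change that goes with the groups' 3'/5' ratio was computed. The slope on the 3'/5' ratio times the difference of the group means (−0.03, against an SD within groups of 0.64) made a median of 0.436% of their changes, and its 95th percentile was 0.944%. With group means this close the product was bound to be small. It covers only a linear effect of this ratio, so other effects of RNA integrity stay open. The 10 ways to split 6 arrays into groups of 3 are too few for a share under 0.05. The real split gave 175 genes and the highest other 0, with the covariate 1872 against 0, and 15 lists against 8; the real split was the 1 of 10 with each of these counts. Over all genes all 10 splits gave 0. At an unadjusted p under 0.05, the split of control 1, control 2 and PRR15 shRNA 2 from the rest gave 2235 of the brighter genes against 1594 for the real split, and 1770 against 1804 over all genes. It left 30.5% of the brighter genes without overlap, against 21.9% for the real split. This grouping places both arrays of high 3'/5' ratio on one side.

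Interferon-stimulated genes among the brighter genes had a median difference of 0.39. A candidate explanation is that cells sensed the hairpin RNA, and another is a loss of PRR15, whose own lower signal did not pass in limma (adjusted p = 0.161 among the brighter genes). Because the control virus carried no shRNA, the hairpin and the targeting of PRR15 come together in the same arrays and cannot be told apart here. The effect of PRR15 was not tested separately for any gene.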
